A study of Mus musculus with 4 samples.

How the data were processed

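Livers of C57BL/6 mice kept on a liquid alcohol diet were compared with livers of pair-fed mice, which were given a control diet. Per the labels' protocols, mice entered the study at 8 weeks of age and were acclimated for 2 weeks. The ethanol content was then raised from 1% to 5%, and the full dose was held for 6 weeks, so that feeding lasted 8 weeks and livers were taken at 16 weeks of age. Hepatocytes were released by collagenase perfusion and non-parenchymal cells were isolated separately, per the labels. The series held 4 samples: 1 single-cell RNA library of mixed liver cells and 1 single-nucleus ATAC library of hepatocytes from each diet, with target yields of 12000 cells and of 3000 to 8000 nuclei. The labels do not give the sex of the mice. Every group therefore had 1 library, and no p-value, standard error or count of changed genes was computed from cells.

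The deposited RNA files held whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. The deposited ATAC files held whole-number counts per peak and nucleus, with a separate peak list for each library. Cell Ranger 3.0.2, Cell Ranger ATAC 1.2.0, Signac 1.2.0, Seurat 4.0 and R 4.0.3 are named in the submitters' processing notes, as is genome build mm10, without the role or order of each. Between 95.8% and 96.2% of the nonzero ATAC values were even numbers, so that counts came in pairs, and counting intervals for ATAC were therefore computed on halved counts. Peak positions were given in mm10 coordinates and are printed 1-based. Gene spans came from a RefSeq table of assembly GRCm38.p6, which holds the same sequence as mm10. It placed 486 of the 488 genes of the fixed lists among 49554 genes with 1 symbol on the autosomes and chromosome X. Exon, intron and transcription start positions were not used here. 1 region of the alcohol peak list was empty and is not analysed here.

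Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 50% mitochondrial UMIs, which left 12182 of 12463 alcohol and 3165 of 3574 control barcodes. Doublets were scored per library against simulated pairs of cells, and the top-scoring expected share was removed (0.8% per 1000 cells, capped at 10%): 1187 alcohol barcodes, or 9.74% of those that passed, and 80 control barcodes, or 2.53%. Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, with scanpy 1.11.5 and igraph 0.11.9. Clusters took a class name from 17 fixed marker lists, with the T cell and NK cell lists merged. A name needed at least 4 markers detected in at least 10% of the cells, a score of at least 0.5, a lead of at least 0.15 over the next class, and no more top genes from another class than from its own. Clusters with hepatocyte markers were split by Xist, a nuclear RNA. Those with fewer than 100 CPM were called nuclear RNA-poor, those above 2000 CPM nuclear RNA-rich, and those in between hepatocyte-like. The first kind held 37.6% of alcohol and 4.18% of control droplets, and the other 5.94% and 1.56%; both stayed out of the hepatocyte comparison.

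UMIs were summed over the cells of a class in each library and scaled to the class total of the library as CPM. Each sum has an exact Poisson 95% interval, each ratio an exact conditional binomial 95% interval, and each share an exact Clopper-Pearson 95% interval. All of these cover counting error only. The log2 ratio of alcohol over control used a pseudocount of 1 CPM, over genes with at least 30 UMIs in both libraries together, while folds were computed without a pseudocount. A gene at 0 in 1 library has a fold against a floor of 3 counts. 28 gene lists covered lipid, alcohol, bile acid and amino acid metabolism, zonation, stress, inflammation, sex bias, the clock, the cell cycle and functions of other liver cells. For each, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries and is no test of the diet. The count of members at least 2-fold apart took only genes whose ratio interval left out 1. For classes other than hepatocytes with at least 50 cells in each library, only genes at least 2-fold above the hepatocytes of the same library, in at least 1 library, entered. Cells with few markers of other classes were those whose share of UMIs in the fixed markers of endothelial, Kupffer and stellate cells, other than their own class, was under 0.1 of the share in that class of the same library.

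For zonation and for relations between cells, hepatocyte-like cells were thinned to 2000 UMIs. Cells with fewer UMIs were left out, 620 in the alcohol and 121 in the control library. Cells were ranked within each library by the mean z-score of the pericentral list minus that of the periportal list and divided into 3 equal bins, or 5 with the outermost compared as an alternative. Members of these lists were left out of the lists compared between bins, and ratios used a pseudocount of 10 CPM. Spearman correlations across cells were set beside those of 200 random lists.

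ATAC peaks of the libraries were compared by an overlap of at least 1 bp and merged into regions with bedtools 2.31.1. Counts in the regions that held a peak of both libraries were summed over each gene span with 2 kb on each side and divided by the library's total in such regions, for genes with at least 200 counts over both libraries. Peaks were called per library, so the covered length is given beside ratios of sums. The number of list members at least 1.5-fold apart was counted.

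Named genes followed a fixed rule. In hepatocyte-like cells it took genes with at least 30 UMIs over both libraries and at least 50 CPM in 1 of them. Of these it took up to 2 per list with the largest absolute log2 ratio, at least 2-fold and with a counting interval leaving out 1, plus the 8 highest and the 8 lowest ratios outside mitochondrial, ribosomal protein, predicted and antigen receptor genes. It always named Hnf4a, Plin2, Cidec, Cyp2e1, Adh1, Aldh2, Fasn, Scd1, Srebf1, Ppara, Cpt1a, Glul, Cyp2f2 and Alb. In other classes it took the 5 highest and 5 lowest ratios and up to 2 genes per list, at least 2-fold apart. For ATAC it took the same hepatocyte genes and the 5 regions with the highest and the 5 with the lowest ratio among those with at least 200 counts. Some genes that the rule took are not reported here.

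The comparisons, gene lists, markers, named-gene rule, cell filter, count minimums and most alternatives were fixed before the data were examined. Several choices came after it. These were the cluster naming limits, which were revised more than once, the Xist limits, the merged T and NK markers, and the doublet share in place of the threshold of scrublet. The ATAC window was also one of them: a window around transcription starts had been planned, and gene spans with flanks replaced it because the gene table gave no strand. The others were the 1.5-fold count for ATAC, the 200-count minimum for gene spans, the zonation pseudocount and its minimum of 20 UMIs per gene, the 0.1 SD distance from a bin boundary, the 200 random lists for correlations, the choice of the lists that lead the text, the lists recomputed within zonation bins and within clusters filled by both libraries at resolution 1 and 2, the cells with few markers of other classes, the comparison of male-biased genes with the control bin in which each was lowest, and the female-biased list without Sult2a1.

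Sums and ratios were tested on simulated counts with 200 genes altered by known folds. The counts followed a Poisson distribution around the mean level of each gene, in pairs for ATAC, with no variation between cells or animals. Coverage of the counting intervals was therefore set by the simulation and checks the computation only. Altered genes were taken only from those with a mean of at least 50 CPM for RNA and 10 CPM for ATAC. Recovery of genes below these levels was not tested. For hepatocyte RNA, over 10651 genes, 95.8% of true ratios lay inside the 95% interval. At each of the folds 1.5, 2, 3 and 4, 100% of altered genes had an interval that left out 1 on the true side. Of unaltered genes, 0.355% came out at least 2-fold apart with an interval that left out 1. A list of 20 genes raised 1.6-fold stood at percentile 100 and an unaltered list at 54.8. For ATAC, over 24397 genes, 95.4% of true ratios were covered and 100% of altered genes were recovered at each of the same folds. Of unaltered genes, 0 came out at least 2-fold apart with an interval that left out 1. A list raised 1.2-fold stood at percentile 100 and an unaltered one at 40.9.

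Alternatives covered the cell filter, doublets, clustering resolution and joint clustering, scaling (nuclear genes only, edgeR TMM factors, median-of-ratios), the mean over cells, thinning, count minimums, the pseudocount, the limit above hepatocytes, bin number, peak overlap and peak frequency, ATAC totals, nucleus depth, gene windows and counts per covered base. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used. Genes of near-identical families (Mup, Serpina1, Cyp2a, Cyp2b, Cyp2c, Sult2a, Sult3a, Acot1 and Acot3, Hspa1a and Hspa1b, H2, Hba and Hbb) can share reads. The handling of such reads is not given in the sources used here, so the split between members of a family is uncertain.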

Results

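Liver cells and hepatocyte nuclei of mice fed alcohol were set against those of pair-fed mice, with 1 library of each kind per diet. The series title names the differing lipid droplet content of hepatocytes as its subject. The alcohol RNA library held 42808601 UMIs over 12463 barcodes, with a median of 2265 UMIs per barcode and a range of 786 to 21681. The control RNA library held 24637681 UMIs over 3574 barcodes, with a median of 4466.5 and a range of 500 to 58749. Median genes per barcode were 999 and 1664.5, and median mitochondrial shares 8.81% and 6.42%, in the alcohol and control library. After filtering and doublet removal 10995 alcohol and 3085 control droplets remained, with medians of 2191 and 4868 UMIs. The ATAC libraries held 54388002 counts in 2822 alcohol nuclei, with a median of 16778 per nucleus and a range of 594 to 112116. The 1924 control nuclei held 51123609 counts, with a median of 23506.5 and a range of 634 to 125043. With 1 library per group, no difference described here has a replicate check, and intervals cover counting error only.

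Hepatocyte-like cells made up 36.8% of the alcohol droplets (95% interval 35.9 to 37.7%; 4049 cells) and 20.7% of the control droplets (19.3 to 22.2%; 638 cells). Clusters with hepatocyte transcripts but little nuclear RNA held a further 37.6% of the alcohol droplets (36.6 to 38.5%) and 4.18% of the control droplets (3.5 to 4.95%). Clusters rich in nuclear RNA held 5.94% (5.50 to 6.40%) and 1.56% (1.15 to 2.06%). Sinusoidal endothelial-like cells, which line the liver capillaries, were 8.88% (8.35 to 9.42%) in the alcohol library and 30.5% (28.9 to 32.2%) in the control library. All clusters outside the hepatocyte kinds together held 19.7% (18.9 to 20.4%) and 73.6% (72.0 to 75.1%).

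Among the 2164 alcohol and 2270 control droplets of those clusters, endothelial-like cells were 45.1% (43.0 to 47.2%) and 41.5% (39.5 to 43.6%). Kupffer-like cells, the resident macrophages, were 11.3% (10.0 to 12.7%) and 9.12% (7.97 to 10.4%). Stellate or fibroblast-like cells were 12.0% (10.7 to 13.5%) and 6.52% (5.54 to 7.61%), and T or NK-like cells 7.53% (6.46 to 8.73%) and 9.60% (8.42 to 10.9%). Monocyte or macrophage-like cells were 7.26% and 8.37%, B-like cells 3.97% and 5.86%, cholangiocyte-like cells 1.80% and 1.59%, mesothelial-like cells 0.970% and 2.38%, and plasmacytoid dendritic-like cells 0.601% and 1.06%. Clusters 13 and 24, left unnamed, held 9.43% and 14.0%. Hepatocytes and non-parenchymal cells were isolated separately, per the labels, so these shares do not give the makeup of the tissue. Depth differed as well: median UMIs were 4866 and 10896.5 in hepatocyte-like, 1625 and 1076 in nuclear RNA-poor, 2457.5 and 7434.5 in endothelial-like, 2227 and 3618 in Kupffer-like and 2643.5 and 6059.5 in stellate-like cells of the alcohol and control library. A limit of 25% mitochondrial UMIs left hepatocyte-like cells at 10.7% of the alcohol and 10.2% of the control droplets, since their median mitochondrial shares were 30.5% and 26.4%.

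**Figure D1:**
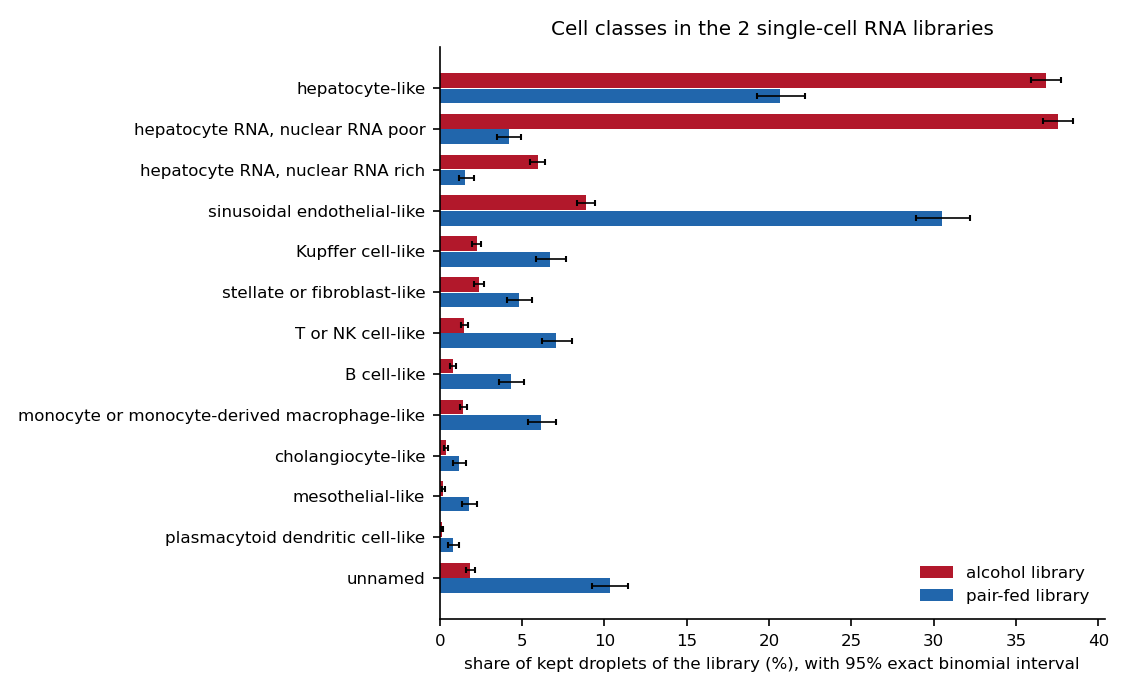
Share of kept droplets in each cell class, in percent of the library, for the alcohol (red) and pair-fed (blue) RNA library, with bars for the share and whiskers for the exact 95% binomial interval. Nuclear RNA-poor droplets with hepatocyte transcripts reached 37.6% of the alcohol library against 4.18% of the pair-fed library, and endothelial-like cells 8.88% against 30.5%.

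In hepatocyte-like cells, 5 of 23 measured fatty acid and triglyceride synthesis genes were at least 2-fold higher in the alcohol library, 1 was at least 2-fold lower and 17 lay within 2-fold. Thrsp, a regulator of lipogenesis, was 3.81-fold higher (95% interval 3.60 to 4.04; 522 against 137 CPM). Elovl6, which elongates palmitate, was 3.20-fold higher (2.90 to 3.54), Fasn, which makes palmitate, 2.62-fold (2.48 to 2.77), and Scd1, which desaturates fatty acids, 1.84-fold (1.80 to 1.88; 1865 against 1012 CPM). Srebf1, a transcription factor of this pathway, stood at 73.8 and 77.2 CPM. The median log2 ratio of the list, 0.67, was at percentile 100 of matched random lists, and resampling its members gave −0.10 to 0.88, which spans 0. The median of all 10651 genes was −0.14, and relative to it the list stood at 0.81. Under TMM scaling the all-gene median was 0.03, and the share of higher genes among those at least 2-fold apart was 54.2% in place of 30.0%; Srebf1 then stood at 0.12 in place of −0.07 and Alb at 0.02 in place of −0.16. Hepatocyte-like cells came from different clusters in the libraries. Clusters 1, 5 and 6 held 39.7%, 22.9% and 20.7% of those of the alcohol library, and cluster 10 held 90.8% of those of the control library.

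Proteins of lipid droplets and lipolysis had a median of −0.08 (percentile 55.3; 1 of 20 at least 2-fold higher). Plin2, the main coat protein of hepatocyte lipid droplets, was at 314 and 273 CPM, 1.15-fold higher (1.1 to 1.2) in the alcohol library. Cidec, which fuses droplets, had 9 and 7 UMIs, a ratio of 0.567 (0.188 to 1.79). G0s2, an inhibitor of triglyceride lipase, was 2.11-fold higher. Cd36, a fatty acid transporter, was 3.85-fold higher (3.38 to 4.41) and Fabp2, a fatty acid binding protein, 2.18-fold higher, while the uptake list had a median of −0.08 (percentile 45.5; 3 higher and 1 lower of 14). Fatty acid oxidation genes had a median of −0.01 (percentile 72.3; 0 higher and 1 lower of 27). Within that list Cpt1a, which admits fatty acids to mitochondria, was at 203 and 183 CPM, Ppara, their nuclear receptor, 1.65-fold lower, and Acot1, an acyl-CoA thioesterase, 2.07-fold lower. Its near-identical relative Acot3 was 5.11-fold higher, and reads can be split between the pair. Apoa4, an apolipoprotein, was 2.21-fold higher, in a lipoprotein list with a median of 0.07 (percentile 80.5; 1 higher and 1 lower of 14). The oxidation, uptake and droplet medians turned positive under TMM scaling, to 0.18, 0.10 and 0.10.

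Cholesterol synthesis genes had a median of 0.39 (percentile 100; 0.53 relative to all genes), with 1 of 21 members at least 2-fold higher and 0 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 2.39-fold higher (2.16 to 2.65), but the bile acid list had a median of −0.18 (percentile 10.0; 1 higher and 3 lower of 15; 0.00 under TMM). Targets of the drug-sensing receptors CAR and PXR had a median of 0.27 (percentile 99.8; 3 higher and 2 lower of 18), which was 0.45 under TMM. Among them Cyp2b10 was 3.35-fold higher (3.01 to 3.74) and Cyp2b13 2.27-fold higher. Urea cycle genes had a median of 0.38 (percentile 98.8) with 0 of 7 members 2-fold apart. NRF2 and antioxidant genes were at 0.19 (percentile 99.5; 1 higher of 20), but at 0.01 with each library clustered alone and 0.37 under TMM. Gluconeogenesis and amino acid genes had a median of 0.18 (percentile 95.9; 0 higher and 2 lower of 16), which was 0.11 with each library clustered alone and 0.36 under TMM. The lower members were Irs2, an insulin receptor substrate, 5.73-fold lower, and Igfbp1, an insulin-repressed binding protein, 3.08-fold lower. Clock output genes were at 0.26 (percentile 99.99; 4 higher and 1 lower of 15), and ranged from 0.09 with each library clustered alone to 0.77 as a mean over cells.

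Alcohol-metabolising enzymes showed no common direction. Cyp2e1, the microsomal ethanol oxidase, was 1.69-fold lower in the alcohol library (1827 against 3082 CPM), Aldh2, which clears acetaldehyde, 1.34-fold lower, and Adh1, the main alcohol dehydrogenase, 1.13-fold higher. The list median was −0.16 (percentile 19.3; 0 higher and 1 lower of 11), and 0.03 under TMM. Pericentral genes had a median of −0.24 (percentile 3.77; 0 higher and 4 lower of 18). Among them Glul, glutamine synthetase, was 2.73-fold lower and Cyp2c54, which has close relatives, 3.27-fold lower, but the median was 0.08 in thinned cells. Cyp2e1 and Glul are both pericentral genes, so a different zonal mix of the recovered cells could also change their pooled levels. This was not tested. Periportal genes were at −0.04 (percentile 40.8; 0 higher and 1 lower of 20; 0.14 under TMM), and Cyp2f2, a periportal cytochrome, was 1.32-fold lower. Hepatocyte transcription factors had a median of −0.21 (percentile 11.2; 0 higher and 2 lower of 20), or 0.01 in thinned cells. Hnf4a, a master factor of hepatocyte identity, was 1.22-fold lower, at 228 against 279 CPM, and Alb, the serum albumin gene, 1.12-fold lower. Under TMM the log2 ratios of Hnf4a, Cyp2f2, Aldh2 and Cyp2e1 were −0.10, −0.22, −0.23 and −0.57. In the main scaling they were −0.29, −0.40, −0.42 and −0.75.

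Unfolded protein and integrated stress response genes were at percentile 0, with a median of −0.48 (−0.34 relative to all genes; 0 higher and 4 lower of 18; −0.30 under TMM). The disulfide isomerase gene Pdia4 was 2.03-fold lower. Acute phase genes, which encode plasma proteins of inflammation, were at −0.38 (percentile 0.04; 0 higher and 3 lower of 24; −0.20 under TMM), with Orm2 5.10-fold lower. Immediate early and heat shock genes were at −0.03 (percentile 71.3; 2 higher and 1 lower of 21; 0.13 under TMM), with Jun 2.78-fold lower. Interferon response genes stood at −0.13 (percentile 58.8; 1 higher and 2 lower of 20; 0.03 under TMM).

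Of 11 male-biased liver genes, 10 were at least 2-fold lower in the alcohol library. Their list had a median of −1.30 (percentile 0; −1.16 relative to all genes); with a pseudocount of 10 CPM the median was −0.80. Slco1a1, a male-biased organic anion transporter, had 5 UMIs in the alcohol and 1643 in the control library, 745-fold lower (ratio 0.000435 to 0.00314). Serpina1e, which has near-identical copies, was 31.6-fold lower. The female-biased list had a median of 0.65 (percentile 100; 0.78 relative to all genes), with 4 of 13 higher, 2 lower and 7 within 2-fold; resampling its members gave −0.12 to 1.18, and without Sult2a1 the median was 0.61 with 3 of 12 higher. Hao2, a hydroxy acid oxidase, was 7.29-fold higher and Cyp2a22, outside the list and of a family with close copies, 7.68-fold. Sult3a1, a female-biased sulfotransferase, was 22.8-fold lower. Sult2a1, another sulfotransferase, was 23.2-fold higher (16.6 to 33.7), but its UMIs lay in 24.4% of the alcohol hepatocyte-like cells at a median of 4866 UMIs and in 24.5% of T or NK-like cells at a median of 1733. The level of Sult2a1 was 82.6 CPM in these hepatocyte-like cells and 152 CPM in T or NK-like cells, so background RNA may account for its level in single cells. Whether the hepatocytes that gave this background differed in Sult2a1 between the libraries was not tested. Xist stood at 674 and 725 CPM in the whole RNA libraries, and 4 Y-linked genes together at 2 and 4 UMIs, so both libraries read as female.

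Of other genes at the ends of the ranking, Slc22a27, of the organic anion transporter family, was 6.93-fold higher and Car14, a carbonic anhydrase, 4.17-fold higher. The major urinary protein genes Mup11 and Mup17, which share sequence with others of the family, were 30.3-fold and 8.28-fold lower. Egfr, the growth factor receptor, was 6.98-fold lower (37.4 against 261 CPM). The globin genes Hbb-bs (3 and 1467 UMIs) and Hba-a1 (0 and 658 UMIs, at least 497-fold lower) are erythroid genes. The Hbb-bs UMIs of the control lay in 1.1% of its 638 hepatocyte-like cells. Mup11, Mup17, Slco1a1, Serpina1e, Sult3a1 and Egfr also led cluster 10, Cyp2b13, Cyp7a1, Hao2 and Cyp2a22 cluster 6, Fasn, Apoa4 and Cyp2f2 cluster 5, and Glul cluster 14, and Sult2a1 and Fabp2 led nuclear RNA-poor clusters, so their ratios and the clusters are not independent.

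Lists of other liver cells were measured in hepatocyte-like cells as well. Stellate activation and matrix genes had a median of −0.94 (percentile 0.08; 0 higher and 3 lower of 5), endothelial adhesion genes −0.37 (percentile 2.06; 0 higher and 4 lower of 14) and antigen presentation genes −0.45 (percentile 1.95; 0 higher and 2 lower of 7). The last turned to 0.24 over genes with at least 100 UMIs. Beside these lists, classes other than hepatocytes held 19.7% of the alcohol and 73.6% of the control droplets, and Ptprc, a leukocyte gene, was at 0.553 CPM (0.286 to 0.966; 12 UMIs) and 1.46 CPM (0.80 to 2.45; 14 UMIs) in hepatocyte-like cells. Inflammatory cytokines were at 0.04 (percentile 89.7; 1 higher and 1 lower of 9) and lipid-associated macrophage genes at −0.05 (percentile 58.0; 1 higher and 2 lower of 12; 0.14 under TMM), the last including Fabp5, a fatty acid binding protein, 3.53-fold lower. Cell cycle genes had a median of 0.56 (percentile 100; 5 higher and 1 lower of 17), from 0.15 as a mean over cells to 1.80 with each library clustered alone. Cluster 22, led by the proliferation genes Mki67 and Top2a, held 2.64% of alcohol and 1.57% of control hepatocyte-like cells.

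**Figure D2:**
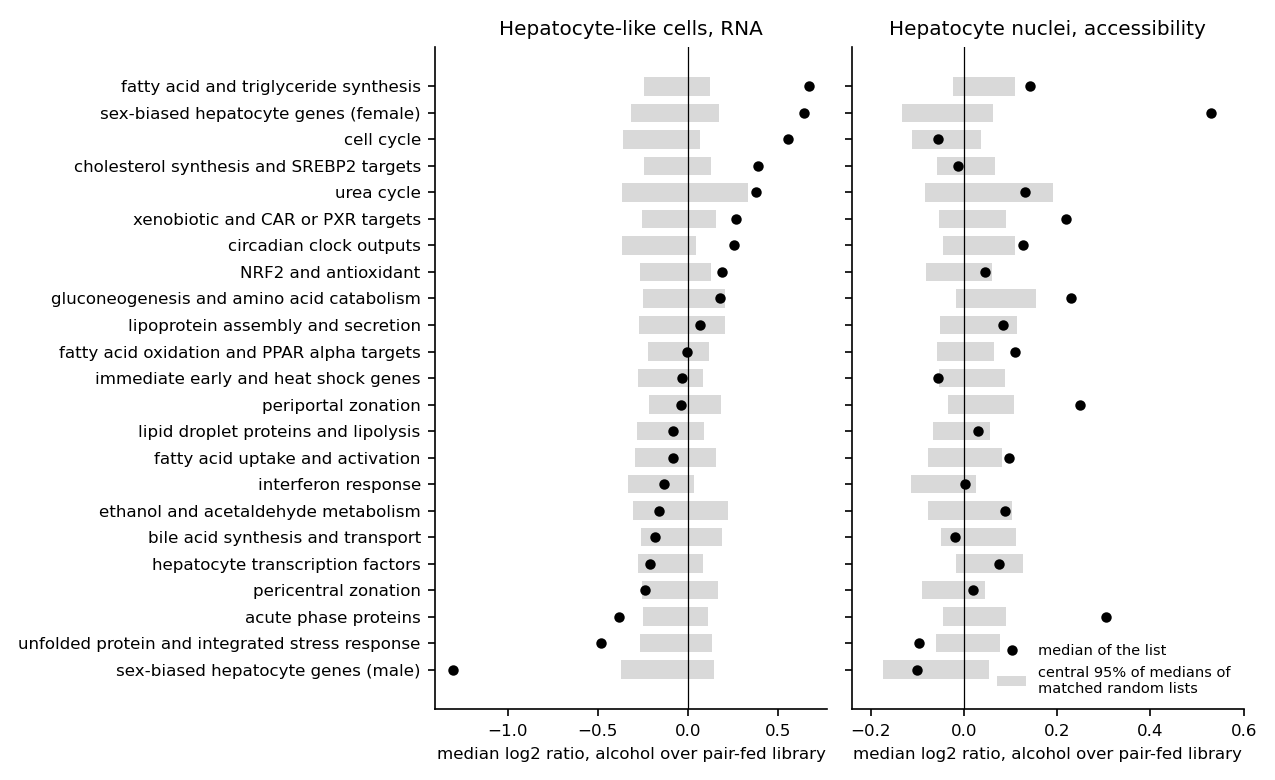
Median log2 ratio of the alcohol over the pair-fed library for each gene list (black points) in hepatocyte-like RNA, left, and in accessibility of hepatocyte nuclei, right, with grey bars for the central 95% of medians of matched random lists. Fatty acid synthesis genes lay at 0.67 in RNA and 0.14 in accessibility, male-biased genes at −1.30 and −0.10, and acute phase genes at −0.38 and 0.31.

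**Figure D3:**
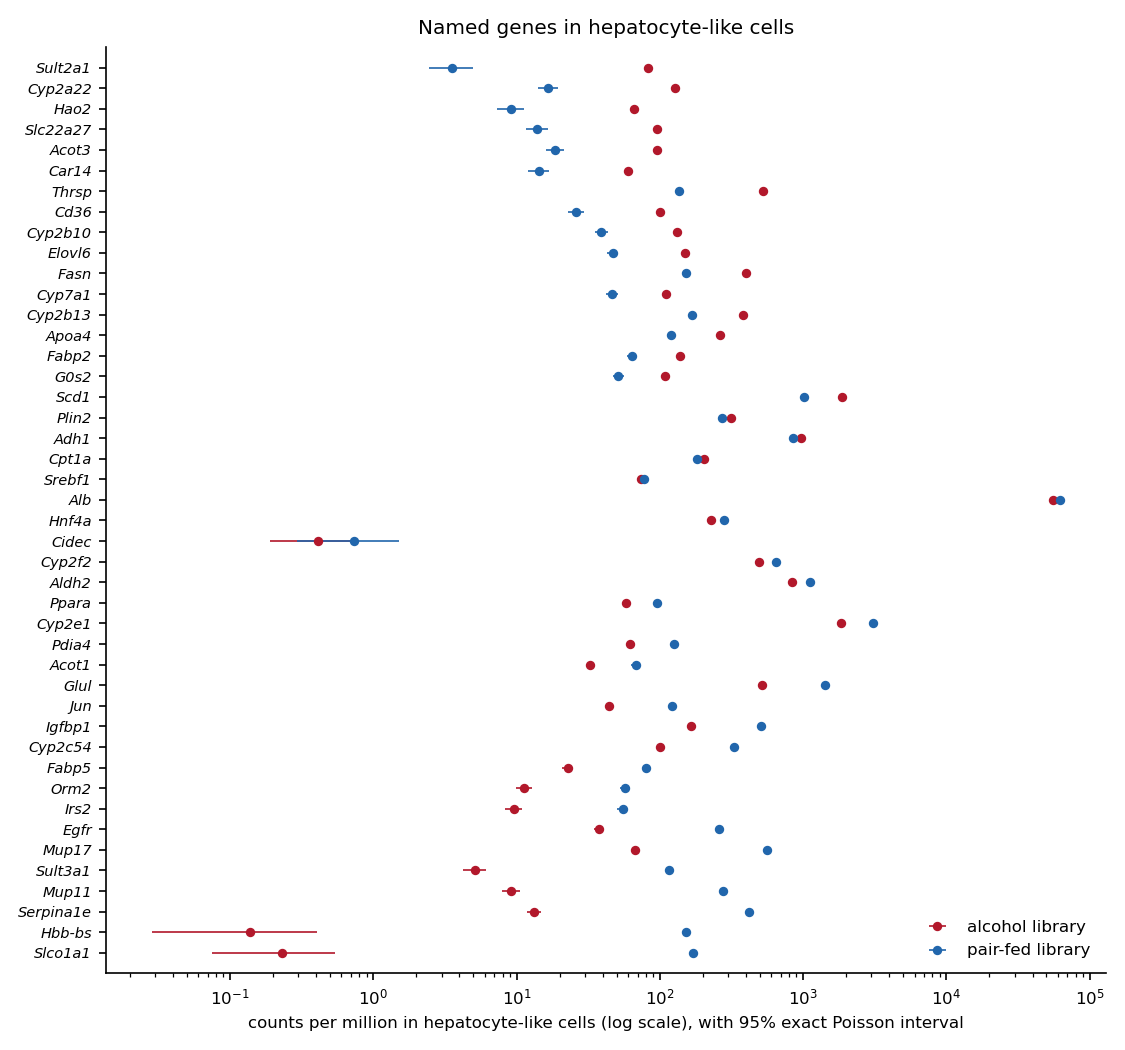
Level of each named gene in hepatocyte-like cells, in CPM on a log axis, in the alcohol (red) and pair-fed (blue) library, with lines for the exact 95% Poisson interval of a single library. Hba-a1, at 0 in the alcohol library, is left out; Thrsp lay at 522 against 137 CPM and Slco1a1 at 0.230 against 172 CPM.

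Zonation along the lobule was compared within each library, since lipid is not stored evenly between zones. Lipogenic genes were higher in the periportal than in the pericentral bin of the alcohol library: Fasn at 568 against 242 CPM (2.34-fold), Thrsp at 734 against 332 CPM (2.21-fold; ratio 0.414 to 0.493) and Scd1 at 2340 against 1289 CPM (1.82-fold). In the control library Fasn was at 159 against 98.8 CPM, Scd1 at 1173 against 724 CPM and Thrsp at 165 against 116 CPM, a ratio that spanned 1 (0.459 to 1.08). Cyp7a1 was higher in the pericentral bin, 24.4-fold in the alcohol and 5.63-fold in the control library, and Cyp2b13 10.9-fold in the alcohol library. Apoa4 was 6.43-fold higher in the periportal bin of the alcohol library, and Plin2 was at 320 and 313 CPM in its pericentral and periportal bin, against 247 and 277 CPM in the control.

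As lists, with medians of pericentral over periportal log2 ratios, fatty acid synthesis was at −0.50 (−0.86 to −0.03) in the alcohol and −0.43 (−0.66 to 0.33) in the control library, and at −0.37 and −0.19 without thinning. Cholesterol synthesis was at 0.34 (0.22 to 0.59) and −0.09 (−0.47 to 0.08), or 0.30 and −0.18 without thinning. Fatty acid oxidation was at 0.33 (0.23 to 0.48) and 0.17 (0.02 to 0.34), acute phase genes at −0.46 and −0.35, bile acid genes at 0.58 and 0.26, xenobiotic genes at 0.38 and 0.10, and droplet proteins at 0.05 and 0.15. Intervals are from resampling list members. Antioxidant genes were at 0.53 and 0.46, ethanol metabolism at 0.35 and 0.27, uptake at 0.15 and 0.29, lipoprotein genes at −0.08 and −0.15, gluconeogenesis at −0.40 and −0.36, the urea cycle at −0.37 and −0.36, and transcription factors at 0.23 and 0.26. Unfolded protein genes were at −0.03 and −0.11, immediate early genes at 0.06 and 0.30, interferon genes at −0.07 and 0.22 (0.019 and 0.32 without thinning), clock genes at −0.04 and 0.27, cell cycle genes at 0.25 and 0.87 (−0.018 and 0.10 without thinning), male-biased genes at 0.63 and 1.1, and female-biased genes at 0.47 and −0.05 (0.43 and 0.26 without thinning). With 5 bins, of which the outermost were compared, the control cell cycle list turned to −0.17 and control xenobiotic genes to −0.018, uptake genes were at 0.31 and 0.14, and unfolded protein genes at −0.051 and −0.42. Alcohol interferon genes then turned to 0.071, alcohol clock genes to 0.080 and control female-biased genes to 0.027. With 3 bins and thinning, some medians rested on few genes, and on different genes in each library. In the control, 4 genes each were measured for the interferon, clock and cell cycle lists, against 16, 15 and 13 in the alcohol library. These 3 control intervals spanned 0. Male-biased medians rested on 4 genes in each library (−1.15 to 1.59 and −0.96 to 3.59), and urea cycle medians on 3. Between the libraries, the fatty acid synthesis list was higher in alcohol by 0.69, 0.84 and 0.61 within the pericentral, middle and periportal bin, and the cholesterol list by 0.85, 0.05 and 0.20, where bins are ranks within each library and not matched zones. A bin is a range of a score, not a cell type: 549 of 3429 alcohol and 72 of 517 control cells lay within 0.1 SD of a boundary. The zonation markers Cyp2e1 and Glul, which are part of the score, were 42.2-fold and 35.2-fold higher in the pericentral bin of the alcohol library and 51.7-fold and 102-fold in the control.

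Relations between lipid droplet genes and other genes were measured across the thinned hepatocyte-like cells of each library. Plin2 went with fatty acid oxidation genes in the control library (Spearman rho 0.262, percentile 98 of random lists) and less in the alcohol library (0.0776, percentile 92); the difference was not tested. Antioxidant genes gave 0.249 with Plin2 in the control and 0.0959 in the alcohol library, both above the central 95% of random lists, which ended at 0.232 and 0.0918. Fatty acid synthesis genes gave 0.148 (percentile 67.5) and 0.0195 (percentile 43), uptake genes 0.120 (percentile 67) and 0.0812 (percentile 95.5), and Hnf4a 0.0380 and −0.00407. The droplet list went with periportal genes in the alcohol library (0.186, percentile 99.5, against 0.104 and percentile 50.5 in the control). With pericentral genes it gave −0.167 there, inside the central 95% of random lists (percentile 3), and 0.0507 in the control. In the control library it went with oxidation genes (0.274, percentile 99; −0.0227 in alcohol) and antioxidant genes (0.264, at the upper end of the central 95% of random lists; −0.00560 in alcohol). Without thinning, Plin2 and oxidation genes gave 0.445 and 0.145, Plin2 and synthesis genes 0.281 and 0.0196, and the droplet list gave 0.418 and −0.0341 with oxidation genes, for the control and alcohol library. Without thinning, Plin2 gave 0.424 and 0.165 with antioxidant genes, 0.243 and 0.182 with uptake genes and 0.298 and 0.0619 with Hnf4a, and the droplet list gave 0.280 and 0.254 with periportal genes, 0.0244 and −0.204 with pericentral genes and 0.412 and 0.0174 with antioxidant genes. Mitochondrial transcripts went the other way. They gave −0.150 and −0.0931 with Plin2 and −0.314 and −0.137 with the droplet list in the control and alcohol library, and without thinning −0.362 and −0.215 with Plin2 and −0.457 and −0.203 with the droplet list.

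In endothelial-like, Kupffer-like and stellate-like cells, the median of the interferon response list was lower and that of the immediate early and heat shock list higher in the alcohol library, while most members lay within 2-fold except for the interferon list of stellate-like cells. The interferon list had a median of −0.80 in endothelial-like (8 of 21 at least 2-fold lower), −0.91 in Kupffer-like (9 of 21 lower) and −1.09 in stellate-like cells (13 of 22 lower), each at percentile 0 and with 0 members at least 2-fold higher. In CPM over genes above hepatocytes 2 of 21, 5 of 21 and 8 of 22 were lower, with medians of −0.51, −0.66 and −0.87. Within cluster 4, which held 91.4% of the alcohol endothelial-like cells, the interferon median was −0.35 on that scale (percentile 28.5; 2 lower of 20). Ifit3, an antiviral interferon target, was 2.44-fold, 3.62-fold and 3.60-fold lower, with Ifi44 2.61-fold lower in endothelial-like and Isg15 3.06-fold lower in Kupffer-like cells. The heat shock list had medians of 0.58 (3 higher of 16), 0.36 (3 of 17) and 0.83 (5 of 16), each at percentile 100 with 0 members lower, and 6, 6 and 10 were higher in CPM over genes above hepatocytes. Hspa1a, an inducible chaperone with a near-identical copy in Hspa1b, was 20.5-fold (17.2 to 24.7), 11-fold and 8.96-fold higher.

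All-gene medians were −0.44, −0.28 and −0.33 in these classes, and relative to them the interferon lists stood at −0.36, −0.63 and −0.76 and the heat shock lists at 1.03, 0.64 and 1.15. Free hepatocyte RNA differed between the libraries beside each of these lists. Alb reached 12673 and 2352 CPM in endothelial-like, 11743 and 2498 CPM in Kupffer-like and 10049 and 2757 CPM in stellate-like cells of the alcohol and control library. Genes above hepatocytes gave 57.8% and 71.3%, 55.2% and 66.5%, and 60.7% and 71.4% of the UMIs of the 3 classes. Cluster 4 held 13.4% of the control endothelial-like cells and cluster 8 held 74.8%, while stellate-like cells lay mostly in cluster 16 (73.8% and 90.5%). Kupffer-like cells lay in cluster 12, of which resolution 2 kept 244 alcohol and 124 control cells together in 1 cluster. Hspa1a, Hspa1b, Klf2 and Cxcl10, stress and immune genes, were among the leading genes of cluster 4. Endothelial markers stood at 22.9% of their endothelial level in stellate-like cells of the alcohol library and 3.44% in those of the control, and at 6.20% and 2.45% in Kupffer-like cells. In the 222 and 143 stellate-like cells with few markers of other classes, where they were at 1.00% and 1.23%, the interferon median was −1.09 (13 lower of 22) and the heat shock median 0.80 (4 higher of 16).

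In Kupffer-like cells, 9 of 17 inflammatory genes were at least 2-fold higher and 7 of 11 antigen presentation genes at least 2-fold lower in the alcohol library. Inflammatory cytokines and chemokines had a median of 1.25 (percentile 100; 9 higher and 0 lower of 17), with Il6, an acute phase cytokine, 12.0-fold higher (68 against 11 UMIs) and Cxcl2, a neutrophil attractant, 6.05-fold higher (4.68 to 7.88). Antigen presentation genes had a median of −1.38 (percentile 0; 0 higher and 7 lower of 11), with the MHC class II genes H2-Eb1 and H2-Ab1 3.51-fold and 3.28-fold lower. The lipid-associated macrophage list was at −0.07 (percentile 89.6; 1 higher and 1 lower of 9): Mmp12, an elastase, was 35.3-fold higher (73 against 4 UMIs) and Trem2, a lipid receptor, 7.31-fold lower (7 against 99 UMIs). Hilpda, a droplet protein, was 13-fold higher and Hspa1b 23.0-fold. Ly6a (5.57-fold), the interferon-inducible Ifi211 (4.25-fold) and Ifi206 (3.73-fold), and Cd207 (3.57-fold) were lower. Cell cycle genes were at −0.66 (percentile 2.19; 0 higher and 5 lower of 10; −0.40 with 0 lower and percentile 2.71 in CPM over genes above hepatocytes), with Pcna 2.23-fold and Stmn1 2.01-fold lower. Clock genes were at 0.52 (percentile 97.7; 1 higher of 3). Dcn, a stellate cell gene, was 13.8-fold higher (235 against 33 UMIs). Resolution 2 put 83 of the 207 control cells and 1 alcohol cell in a cluster of their own. In the cluster that both libraries filled, with 244 and 124 cells, inflammatory genes were at 1.37 (11 higher of 17), antigen presentation at −1.30 (1 higher and 6 lower of 8), heat shock genes at 1.26 (13 higher of 16), interferon genes at −0.70 (5 lower of 17), lipid-associated genes at 0.13 (1 higher and 1 lower of 9) and cell cycle genes at −1.52 (5 lower of 8). Trem2 was 7.72-fold and Cd207 2.83-fold lower there, Cxcl2 13.9-fold higher, and Mmp12 20.3-fold higher (5.41 to 171; 73 against 2 UMIs). In the 219 and 199 cells with few markers of other classes cell cycle genes were at −1.14 (5 lower of 9), and Dcn was at 14 against 32 UMIs. Lipid-associated genes were at −0.16 (1 lower of 8) in those cells, where Mmp12 no longer counted as higher.

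Endothelial-like cells had adhesion and capillarization genes at −0.61 (percentile 0.81; 2 higher and 1 lower of 21), with 4 higher and 0 lower in CPM over genes above hepatocytes and percentile 8.52 among genes at 5 times the hepatocyte level. Among them Icam1, an adhesion molecule, was 2.52-fold higher and Nos3, endothelial nitric oxide synthase, 2.03-fold lower. Hspa1b (34.7-fold), the stress factor Atf3 (4.36-fold), Igfbp5 (3.56-fold), the clock output Dbp (3.52-fold) and the cell cycle inhibitor Cdkn1a (2.11-fold) were higher. Mmp14 (3.45-fold), Akap2 (2.92-fold), Rnf20 (2.84-fold), Hoxb4 (2.75-fold) and Ccnd2, a cyclin (2.70-fold), were lower. Their cell cycle list was at −0.28 (percentile 72.9; 1 higher and 1 lower of 9) and their clock list at −0.43 (percentile 55.9; 1 higher and 1 lower of 5).

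Stellate-like cells had matrix and activation genes at −0.34 (percentile 33.1; 1 higher and 0 lower of 17), with Loxl1, a collagen crosslinker, 2.16-fold higher. Cell cycle genes were at 0.40 (percentile 97.9; 1 higher of 5), with Cdkn1a 4.81-fold higher, and clock genes at 0.12 (percentile 90.7; 1 higher of 4), with Dbp 7.97-fold higher. Carmn (5.89-fold), Cacnb2 and Dach1 (5.55-fold each), the laminin gene Lama1 (5.03-fold), Cd74 (6.11-fold) and C6 (2.56-fold) were lower. Hspa1b was 19.0-fold higher. The endothelial genes Fabp4 (209 against 2 UMIs; 113-fold, 30.9 to 939), Lyve1 (71 against 1; 76.7-fold) and Rasip1 (68 against 4; 18.4-fold), and Cyp26b1 (144 against 3; 51.9-fold), which led endothelial cluster 4, were higher in stellate-like cells of the alcohol library. In the cells with few markers of other classes these genes and Cdkn1a no longer passed the count minimum or the level above hepatocytes, and fewer than 3 cell cycle or clock genes did.

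**Figure D4:**
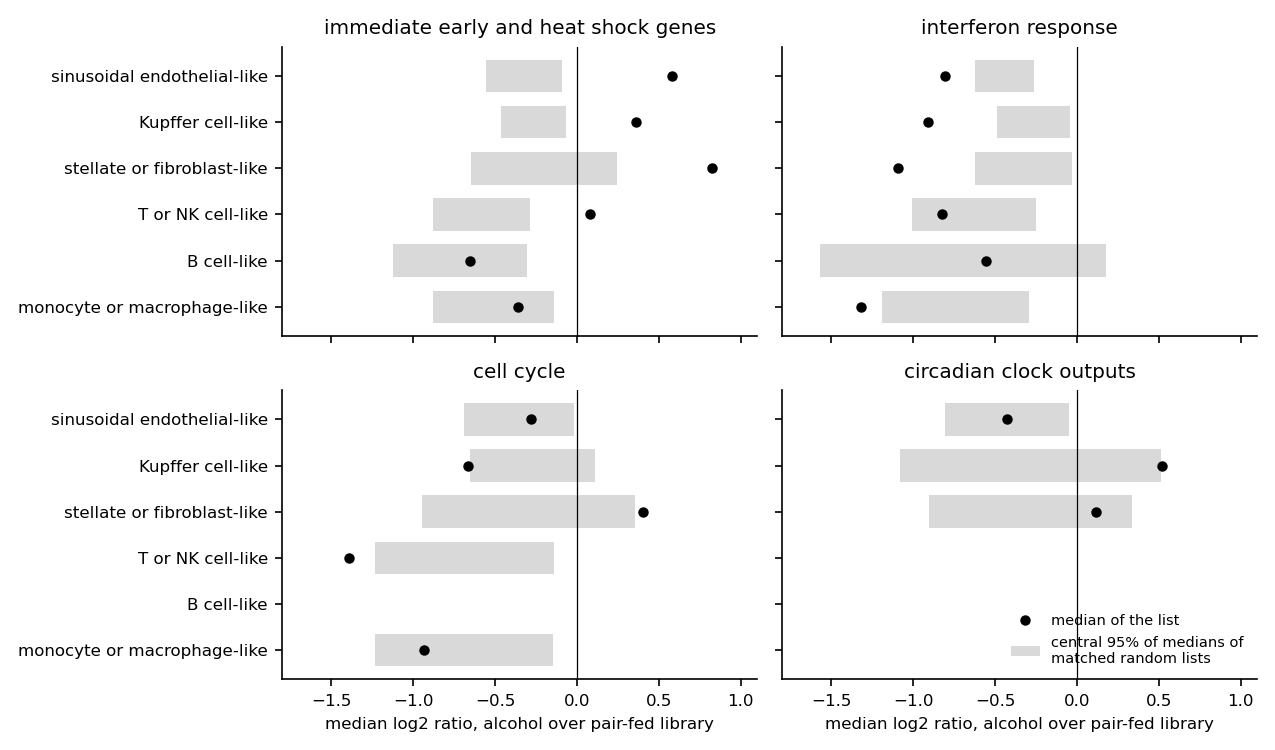
Median log2 ratio of the alcohol over the pair-fed library for 4 gene lists in each non-hepatocyte class (black points), with grey bars for the central 95% of medians of matched random lists; a class with fewer than 3 measured genes of a list has no point. Interferon medians were −0.80, −0.91 and −1.09 and heat shock medians 0.58, 0.36 and 0.83 in endothelial-like, Kupffer-like and stellate-like cells.

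Open chromatin of hepatocyte nuclei covered much the same regions in both libraries. Of 131260 alcohol peaks 81.9% (81.6 to 82.1%) overlapped a control peak, and of 128960 control peaks 85.7% (85.5 to 85.9%) overlapped an alcohol peak. Median peak widths were 654 and 655 bp, and the peaks covered 156 and 147 Mb. The 104794 shared regions held 99.3% and 99.4% of the counts, at 360 and 356 counts per kb of covered length. Among 58577 shared regions with at least 200 counts, 1.15% were at least 2-fold higher and 1.98% at least 2-fold lower in the alcohol library.

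The largest ratios of regions went with the length that was called. Regions inside Stt3b (chromosome 9, 115290239 to 115293094) and Dgcr2 (chromosome 16, 17839643 to 17843077) had 217 and 211 counts in the alcohol and 0 in the control library. They were called over 2856 and 3435 bp in the alcohol but only 23 and 7 bp in the control library. Reads outside the peaks of a library were not counted, so no fold is given for these regions. A pair of regions inside Cux2, a female-biased transcription factor gene (chromosome 5, 121991521 to 121994906 and 121981624 to 121986231), were 65.9-fold and 20.3-fold higher, and 1.78-fold and 1.00-fold per covered base. A region inside Prlr, the prolactin receptor gene (chromosome 15, 10185565 to 10190067), was 50.8-fold higher and 1.29-fold per covered base. In the other direction, a region 2159 bp from Egfr (chromosome 11, 16916066 to 16922844) had 0 and 525 counts over 16 and 6779 bp, so no fold is given for it either. Regions inside Mug1 (chromosome 6, 121848428 to 121851848), Cpeb2 (chromosome 5, 43289723 to 43292076) and Epas1 (chromosome 17, 86824761 to 86831403) were 28.5-fold, 17.3-fold and 14.7-fold lower, over 156 and 3421 bp, 239 and 2354 bp and 680 and 6514 bp. Per covered base they were 1.24-fold, 1.68-fold and 1.46-fold lower. A region 39072 bp from the predicted gene Gm19022 (chromosome 9, 112828597 to 112829817) was 18.9-fold lower, and 5.13-fold per covered base.

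Median accessibility of the female-biased, acute phase, periportal, gluconeogenic and xenobiotic lists was higher in the alcohol nuclei. The female-biased list had a median of 0.53 (percentile 100; 6 at least 1.5-fold higher and 1 lower of 14), acute phase genes 0.31 (percentile 100; 4 higher of 23), periportal genes 0.25 (percentile 100; 0 higher of 20), gluconeogenesis genes 0.23 (percentile 99.97; 1 higher of 16) and xenobiotic genes 0.22 (percentile 100; 4 higher of 19). Per covered base these medians were 0.25, 0.15, 0.15, 0.21 and 0.20, with 1, 4, 0, 1 and 1 members at least 1.5-fold higher. Over all 24397 genes the median was −0.04, with the 5th to 95th percentile from −0.43 to 0.26. Fatty acid synthesis genes were at 0.14 (percentile 99.8; 1 higher and 1 lower of 24), and at 0.07 (percentile 87.5) per covered base. In RNA the acute phase median was −0.38, and 21 of its 24 genes lay within 2-fold.

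Among single genes, Adh1, the alcohol dehydrogenase gene (chromosome 3, 138277585 to 138290698), had 12964 and 7325 counts over 21490 and 21322 bp, 1.67-fold higher (1.6 to 1.74). Log2 ratios were 0.86 for Cyp2b13 (chromosome 7, 26061388 to 26096197; 26435 and 18187 bp covered), 0.84 for Cyp2a22 and for Hao2, 0.80 for Slc22a27, 0.76 for G0s2, 0.59 for Cd36, 0.51 for Sult2a1 and 0.44 for Thrsp (chromosome 7, 97412933 to 97417550; 14263 and 13267 bp). Elovl6 was at 0.63 over 104206 and 54319 bp, and at −0.24 per covered base. Egfr (chromosome 11, 16752203 to 16913907) was at −0.99 over 95108 and 156569 bp, Sult3a1 at −0.88, Slco1a1 (chromosome 6, 141907281 to 141946962) at −0.77 over 34838 and 45978 bp, Cyp2c54 at −0.61 and Glul at −0.47. Closer to 0 lay Acot3 (0.44), Cyp2b10 and Apoa4 (0.43 each), Cyp2f2 (0.33), Orm2 (0.31), Cidec (0.29), Car14 (0.26), Irs2 (0.18), Ppara (0.15), Fasn (0.09), Aldh2 (0.03) and Cpt1a (0.01). On the other side of 0 were Srebf1 (−0.01), Plin2 (−0.02), Scd1 (−0.04), Pdia4 (−0.07), Cyp2e1 (−0.17), Cyp7a1 (−0.18), Alb (−0.23), Igfbp1 (−0.25), Jun (−0.27), Fabp5 (−0.32) and Fabp2 (−0.34). Hnf4a (chromosome 2, 163506811 to 163572907) had 23807 and 22415 counts. These ratios are of sums over peaks called separately in each library. Per covered base Sult2a1 was at 0.26, and Srebf1 (0.14), Fabp5 (0.10), Plin2 (0.090), Pdia4 (0.068), Cyp2e1 (0.066) and Scd1 (0.035) turned positive.

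Remaining lists had smaller ratios. Fatty acid oxidation genes were at 0.11 (percentile 99.97; 2 higher of 27), uptake genes at 0.10 (percentile 98.8), clock genes at 0.13 (percentile 99.0; 0.05 per covered base), urea cycle genes at 0.13 (percentile 89.5), ethanol metabolism at 0.09 (percentile 95.1), lipoprotein genes at 0.08 (percentile 89.2; 0.13 per covered base), transcription factors at 0.08, antioxidant genes at 0.04 and droplet genes at 0.03. Unfolded protein genes were at −0.10 (percentile 0.09) and immediate early genes at −0.06 (percentile 2.15), but at 0.14 and 0.056 per covered base. Male-biased genes were at −0.10 (percentile 18.7; 0 higher and 2 lower of 11). Cholesterol genes were at −0.01, bile acid genes at −0.02, pericentral genes at 0.02, interferon and inflammatory genes at 0.00, cell cycle genes at −0.06, and the macrophage and antigen presentation lists at −0.04. Spans of hepatocyte marker genes had 1.07-fold the counts share in the alcohol library, those of stellate markers 0.819-fold, endothelial markers 0.949-fold, Kupffer markers 1.11-fold and monocyte markers 1.22-fold; the stellate activation list was at −0.13 and the endothelial list at −0.00.

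RNA and accessibility ratios were weakly related across 10202 genes (Pearson r 0.233, Spearman rho 0.156), and genes are not independent replicates. Of 300 genes at least 2-fold apart in RNA, the 104 higher ones had a median accessibility ratio of 0.13 and the 196 lower ones −0.09, and 69.0% had the same direction in both measures. Per covered base r was 0.0446 and rho 0.0159, the medians of the higher and lower genes were 0.082 and −0.0079, and 55.0% had the same direction. Over the 418 genes of the fixed lists r was 0.351 and rho 0.262, and 0.156 and 0.127 per covered base. Of those at least 2-fold higher in RNA, the median per covered base was 0.25, and of those lower 0.068. Among named genes at least 2-fold lower in RNA, accessibility per covered base was −0.41 for Sult3a1, −0.34 for Cyp2c54, −0.32 for Igfbp1, −0.31 for Slco1a1, −0.21 for Egfr, −0.20 for Glul, −0.15 for Jun and −0.016 for Mup11, but 0.36 for Serpina1e, 0.22 for Irs2, 0.14 for Orm2, 0.10 for Fabp5, 0.068 for Pdia4 and 0.013 for Acot1. Among those higher in RNA, it was 0.56 for Slc22a27, 0.40 for Thrsp, 0.39 for Cyp2b13, 0.37 for Cyp2b10 and G0s2, 0.34 for Hao2, 0.33 for Cd36, 0.28 for Apoa4, 0.26 for Car14 and Sult2a1, 0.14 for Fasn, 0.13 for Acot3 and 0.086 for Cyp2a22, but −0.24 for Elovl6, −0.23 for Fabp2 and −0.12 for Cyp7a1.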

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

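Of the tests given here, the one on the mitochondrial share was chosen only after the result was seen; the one on free RNA was written beforehand, although Sult2a1 levels in these droplets were already known.

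Droplets kept out of the comparisons stood out because they took a larger share of the alcohol than of the control library: nuclear RNA-poor droplets were 37.6% of the alcohol and 4.18% of the control library, and nuclear RNA-rich droplets 5.94% and 1.56%. For most of the nuclear RNA-poor droplets, mitochondrial transcripts argue against shallow sequencing of whole hepatocytes as the source. Pooled over all such alcohol droplets, the mitochondrial share was 0.227 of that in hepatocyte-like cells (6.54% against 28.8% of UMIs). Shallow sequencing alone would leave it near 1. Clusters 2, 3 and 7 had median shares of 1.55%, 5.14% and 3.04% over both libraries. Cluster 11, with 13.1% of the alcohol droplets of this kind, had a median of 23.8%, so the argument does not cover it. Free RNA of the library is a candidate source: over 155 hepatocyte transcripts, lymphocyte-like droplets of the alcohol library were closer in their proportions to these droplets than to hepatocyte-like cells, by a median absolute log2 difference of −0.18 (−0.23 to −0.13; 0.138 against 0.319). Whether the diet, the animal or the preparation released more such RNA was not tested, since each diet had 1 library.

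Medians of the cell cycle list had opposite signs between classes of the same pair of libraries, a difference that was not tested: −0.66 in Kupffer-like and −1.39 in T or NK-like cells, against 0.56 in hepatocyte-like (5 higher and 1 lower of 17) and 0.40 in stellate-like cells (1 higher of 5). In CPM over genes above hepatocytes the first 2 were −0.40 and −0.89, with 0 of 10 and 2 of 9 members at least 2-fold lower in place of 5 and 6. In cells with few markers of other classes, chosen after the result was seen, they were −1.14 and −1.30 in CPM over all genes, while the stellate-like list was not measured there. T or NK-like cells lay in different clusters, with 100% of the alcohol cells in cluster 21 and 91.3% of the control cells in cluster 18. In the alcohol library the cell cycle genes Ube2c and Birc5, chosen after their values were seen, were at 18.7 and 13.7 CPM in nuclear RNA-poor droplets, against 8.57 and 5.48 CPM in hepatocyte-like cells.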

How the results depend on the processing

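Counts per covered base, the female-biased list without Sult2a1, gene spans without flanks, both gene ends, the further clustering settings for hepatocyte genes, cells with few markers of other classes, the Kupffer-like cluster of resolution 2 that both libraries filled, and the RNA settings used for the relation with accessibility were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each group had 1 library, all numbered replicate 1. Windows of 2 kb or 1 kb around transcription starts, and gene bodies with 2 kb upstream (also planned for the relation with RNA), were not run for lack of strand. Among the results that answer a comparison, 120 values stayed within their error and 26 moved under alternatives fixed beforehand, and 83 stayed and 20 moved under those added later. Among all others these were 1187, 350 and 5 reversed, and 553, 117 and 4 reversed. The error was the counting interval for shares and genes and the interval from resampling for list medians and zonation. For correlations across cells it was a width from random lists or a fixed one. Only a result that stood apart in the main setting could count as reversed, so other sign changes are among those that stayed or moved. By scaling alone, 9 medians of the hepatocyte lists changed sign and 19 did not. At no more than 25% mitochondrial UMIs, hepatocyte-like shares were 10.7% (alcohol) and 10.2% (control) and nuclear RNA-poor droplets 52.3% of alcohol, because the limit removes mitochondria-rich cells. At 1000 UMIs, nuclear RNA-poor droplets were 3.00% of control, and endothelial-like cells 49.6% and 49.7% of non-hepatocyte cells in alcohol and control. With doublets kept, nuclear RNA-poor droplets were 34.6% of alcohol, and the alcohol endothelial share 41.0%. At resolution 0.5, alcohol hepatocyte-like cells were 35.6%, control nuclear RNA-poor droplets 1.46% and the alcohol endothelial share 42.4%; at resolution 2, control hepatocyte-like cells were 15.5% and nuclear RNA-poor droplets 6.32%. Each library clustered alone gave the control 9.34% hepatocyte-like, 5.58% nuclear RNA-poor and 37.4% endothelial-like. The hepatocyte cholesterol median was 0.57 under TMM and 0.57 under median-of-ratios factors, and the male-biased median −0.80 at 10 CPM pseudocount. Hepatocyte antigen presentation reversed to 0.10 at 25% mitochondrial UMIs, 0.14 in thinned cells and 0.24 at 100 UMIs. With CPM over genes above hepatocytes, interferon medians were −0.66 (Kupffer-like) and −0.51 (endothelial-like), and the endothelial heat shock median 0.89. In cells with few markers of other classes and CPM over genes above hepatocytes, interferon medians were −0.68 (Kupffer-like) and −0.48 (endothelial-like), heat shock medians 0.89 (endothelial-like) and 1.09 (stellate-like), and Kupffer-like Dcn, itself such a marker, reversed to −0.047 in CPM over all genes. In the shared Kupffer-like cluster of resolution 2, the heat shock median was 1.26 and the interferon median −0.70, or 1.45 and −0.52 in CPM over genes above hepatocytes. T or NK-like heat shock genes reversed to −0.14 at 5 times the hepatocyte level, and the alcohol zonation of cell cycle genes to −0.018 without thinning. Peak overlap was 68.9% (alcohol) and 70.1% (control) at 50% of both peaks, and 98.6% and 80.5% for peaks in 5% of nuclei. Per covered base, accessibility of unfolded protein genes (0.14), immediate early genes (0.056) and Elovl6 (−0.24) reversed, and the acute phase and female-biased medians were 0.15 and 0.25. For RNA against accessibility, r and rho were 0.0446 and 0.0159 per covered base, 0.195 and 0.110 with all hepatocyte-marker clusters, 0.166 and 0.106 thinned, and 0.182 and 0.123 with no UMI minimum; rho was 0.135 with doublets kept and 0.123 at 10 CPM pseudocount. Some counts of hepatocyte list members at least 2-fold apart moved by over 1.5 times and by at least 2 genes. TMM and median-of-ratios factors both gave 9 higher fatty acid synthesis genes in place of 5, 3 higher cholesterol genes in place of 1, 2 higher ethanol and 2 higher periportal genes in place of 0, 5 higher and 0 lower xenobiotic genes in place of 3 and 2, and 2 lower endothelial genes in place of 4. Nuclear scaling gave 3 higher cholesterol genes. Fatty acid synthesis had 9 higher as a mean over cells and 8 when thinned. Cell cycle had 3 higher in those settings, 10 with doublets kept and 12 with each library clustered alone, in place of 5. Pericentral genes had 1 lower at 25% mitochondrial UMIs, as a mean over cells and thinned, and 2 in deep clusters, in place of 4. Thinned cells had 5 lower acute phase genes in place of 3, and 6 of 6 measured male-biased genes lower in place of 10 of 11. Antioxidant genes had 5 higher over all hepatocyte-marker clusters in place of 1, and acute phase genes 2 higher there and with each library clustered alone in place of 0. Per covered base, lower counts in accessibility were 0 in place of 3 for antioxidant genes, 1 in place of 3 for stellate genes and 0 in place of 2 for male-biased and interferon genes. Unless stated, the cause was not tested. Depth limits genes with few UMIs, such as Cidec, with 9 and 7.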

Other observations

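The tests of explanations for the interferon and sex-biased lists, the clusters of resolution 2, the cells with few markers of other classes, the counts per covered base and the list without Sult2a1 were chosen only after the results were seen; the gene lists and the scalings over genes above hepatocytes were fixed beforehand.

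The chaperone gene Hspa1a was higher in lymphocyte-like and monocyte-like cells of the alcohol library, while the heat shock list differed between these classes. Hspa1a, at 44 UMIs in T or NK-like and 49 in B-like cells of the alcohol library, was at 0 in those of the control, at least 54.9-fold and 49.9-fold higher, and in monocyte-like cells it was 30.0-fold higher (105 against 8 UMIs). The near-identical Hspa1b was 142-fold higher in T or NK-like (38 against 1 UMI; 24.0 to 5767) and 28.2-fold in monocyte-like cells (37 against 3). In T or NK-like cells the chemokine genes Ccl3 and Ccl4 were 6.27-fold and 5.16-fold higher, in an inflammatory list with a median of 1.16 (percentile 100; 3 higher and 0 lower of 6), while Ifi47 and Gbp7, interferon-inducible GTPases, were 6.33-fold and 5.37-fold lower. The replication genes Mcm3 (7.88-fold; 2 against 59 UMIs) and Mcm6 (2.30-fold) were lower, in a cell cycle list at −1.39 (percentile 0.52; 0 higher and 6 lower of 9), or −0.89 with 2 lower in CPM over genes above hepatocytes. Their heat shock list was at 0.08 (percentile 99.99; 4 higher of 16), interferon at −0.83 (percentile 12.0; 5 lower of 12, or 3 in CPM over genes above hepatocytes), lipid-associated macrophage genes at −0.60 (percentile 65.2; 1 higher of 5, Cd9 at 2.45-fold) and antigen presentation at −0.74 (percentile 28.1; 0 of 4 apart). Zmynd8 (10.3-fold), Rgs10 and Dido1 (7.74-fold each) and Tcrg-C2 (7.32-fold) were lower too. Endothelial genes were higher in the same cells: Fabp4 65.5-fold (35 against 2 UMIs), Aqp1 11.2-fold and Fcgr2b 8.74-fold. In the 156 and 215 cells with few markers of other classes these and Cd9 were no longer measured, and the inflammatory median was 0.21 (2 higher and 1 lower of 5). Cluster 21 held 100% of the alcohol and cluster 18 held 91.3% of the control T or NK-like cells. Ccl4, Gzma, Gzmb and Xcl1 were among the leading genes of cluster 21 only, and Trbc1 and Trbc2 of cluster 18 only, while Cd3d and Cd3g led both. The ratios may therefore compare different mixes of T and NK cells, which was not tested. The all-gene median was −0.66, with Alb at 20454 and 3119 CPM.

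B-like cells had antigen presentation genes at −1.04 (percentile 1.66; 8 lower of 10), or −0.50 with 1 lower in CPM over genes above hepatocytes, and at percentile 7.85 among genes at 5 times the hepatocyte level. Among them Ciita, the master regulator of MHC class II, was 3.80-fold and the costimulatory receptor Cd40 4.36-fold lower (3 against 40 UMIs). The signalling kinase gene Btk had 0 and 44 UMIs, at least 4.80-fold lower, and Snx30, Pum3, Rbm38 and Tcf20 were at least 4.25-fold, 3.49-fold, 3.38-fold and 3.27-fold lower. Nfkbia (2.26-fold) and Xist (2.21-fold) were also lower, and Cnpy2 (5.19-fold), Etfb (4.45-fold), Dnajb1 (4.00-fold) and Mrpl17 (3.06-fold) higher. Etfb was also among the leading genes of nuclear RNA-poor cluster 2. Background RNA was not tested as the source of its level in B-like cells. Their heat shock list was at −0.65 (percentile 68.7; 2 higher and 4 lower of 14, or 2 and 1 in CPM over genes above hepatocytes) and interferon at −0.56 (percentile 66.6; 1 lower of 4), beside an all-gene median of −0.80 and Alb at 22297 and 4918 CPM. Monocyte-like cells, whose cluster was led by MHC class II genes, had interferon genes at −1.32 (percentile 0.42; 0 higher and 11 lower of 13), or −0.84 with 2 lower in CPM over genes above hepatocytes, and at percentile 6.62 among genes at 5 times the hepatocyte level. Among them Ifit3 was 9.62-fold (2 against 44 UMIs) and Oasl2 6.23-fold lower. Camp, Ngp and Elane, granulocyte genes, were at 0 in the alcohol library, at least 134-fold, 50.3-fold and 38.0-fold lower, as were Rspo3 (15.3-fold) and Fcnb (at least 13-fold). Ccl5 (9.30-fold), Trem2 (5.68-fold), Stmn1 (2.34-fold) and Ciita (2.12-fold) were lower, and Marco (11.2-fold), Ccl17 (8.13-fold), Cd36 (2.41-fold) and Cxcl2 (2.33-fold) higher. Marco is one of the fixed Kupffer markers, and Rspo3 was among the leading genes of endothelial cluster 19. RNA of other cell classes was not examined in monocyte-like cells. Sult2a1, at 52 against 1 UMI, was 119-fold higher in these cells, which should lack it. Their other medians were −0.36 for heat shock (percentile 82.5; 3 higher and 2 lower of 17, or 3 and 0 in CPM over genes above hepatocytes), −0.34 for inflammatory genes (percentile 86.8; 1 and 1 of 13), −0.65 for lipid-associated genes (percentile 43.6; 1 and 1 of 8), −0.74 for antigen presentation (percentile 2.87; 1 lower of 9) and −0.94 for the cell cycle (percentile 19.3; 1 lower of 9), beside an all-gene median of −0.66.

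The interferon median was lower in endothelial-like, Kupffer-like and stellate-like cells of the alcohol library, which may reflect the diet or the preparation. Dilution by free hepatocyte RNA as the whole cause is argued against, since it lowers every gene of a class by 1 factor, and in CPM over genes above hepatocytes, which removes that factor, the medians were −0.51, −0.66 and −0.87 with a highest upper bound of −0.25; T or NK-like and B-like cells were at −0.31 and −0.02 (−1.48 to 0.61). A difference in the clusters that fill a class is argued against for stellate-like cells, at percentile 0 within cluster 16 (−0.81), as is RNA of endothelial cells, whose markers were at 22.9% of their own level in these alcohol and 3.44% in these control cells, since without the cells rich in it the median was −0.81 (−1.14 to −0.59), and for Kupffer-like cells, where resolution 2 split off a cluster of 83 control cells and 1 alcohol cell and the list was at percentile 0.03 (−0.52) within the cluster that both libraries filled. For endothelial-like cells that explanation and a difference within cells cannot be told apart: the list was at percentile 28.5 in cluster 4 (−0.35; 892 alcohol and 126 control cells) and 0.805 in cluster 19 (−0.53), and at 2.08 and 0.630 in the shared clusters of resolution 2. Alcohol against an effect of the animal or of cell isolation stays open and untested, and heat shock medians, which were higher in the same clusters (0.83 and 0.35 in endothelial-like, 1.45 in Kupffer-like and 1.1 in stellate-like cells), leave stress during isolation among the candidates.

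Of 11 male-biased genes 10 were at least 2-fold lower in hepatocyte-like cells of the alcohol library, and of 13 female-biased genes 4 were higher and 2 lower, with a median of 0.65 (−0.12 to 1.18) that was 0.61 without Sult2a1. Mice of different sex are argued against by Xist, at 0.930 times the control level, with 2 and 4 UMIs of Y-linked genes. Xist, at 674 and 725 CPM, and the near lack of Y-linked UMIs mark both libraries as female. The sex-biased lists therefore do not compare male livers. A different zonal mix of the recovered hepatocytes cannot be told apart from a difference within cells for the male-biased list. Of 11 genes, 8 were below the control zonation bin in which each was lowest, but the median of −0.32 had an interval of −0.63 to 0.33. These ratios used a pseudocount of 10 CPM, which draws those of genes at low levels toward 0. Slco1a1 was at 0.230 against 19.8 CPM in that bin and Serpina1e at 13.3 against 309 CPM. Cyp2d9 (8.94 against 3.97 CPM), Cyp7b1 (16.0 against 7.15 CPM) and Elovl3 (2.53 against 0 CPM) lay above it. For the female-biased list, accessibility in separately prepared nuclei was at percentile 100 (0.53, with 6 of 14 members at least 1.5-fold higher). This argues against a difference between the RNA preparations alone. That percentile is of sums over peaks called per library. Per covered base the median was 0.25 with 1 such member, so the argument is weaker on that scale. For the male-biased list, at percentile 18.7, a difference between the RNA preparations alone cannot be told apart from a difference in the animals. Alcohol against an effect of the animal stays open and untested, since each diet had 1 library.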
